A study of Homo sapiens and Mus musculus with 78 samples.

How the data were processed

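The analysis began from the processed files that the authors deposited. The submitters' processing notes name STAR and RSEM for RNA-seq, BWA and SAMtools for alignment of the other assays, MACS2 for peaks and DESeq2 for differential expression, with the builds GRCh38 for human and GRCm38 for mouse. Their versions and parameters, the trimming of reads, the caller of the HiChIP loops and the design of the DESeq2 test are not given in the sources used here. The deposited RNA-seq files hold, per the file headers, RSEM expected counts, TPM and FPKM for each of 28264 human or 25140 mouse genes, and only the expected counts were used. The deposited peak files hold, per the file headers, a signal value, which MACS2 makes as the ratio of the pileup to that of the control, and p- and q-values as negative logarithms. The lowest negative log10 q in the lists is 2. The deposited loop files hold, per the file headers, a read count, a signal expected for the distance and a false discovery rate for pairs of 5 kb bins on 1 chromosome, all below a rate of 0.01. One file labelled as H3K4me3 of Vector was kept under its label, since 48.2% of its peaks lay at gene ends and 4.77% in H3K27me3 peaks of Vector.

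Expected counts were rounded to whole numbers. The libraries of a set (first THP-1 set, batch2, embryoid bodies) entered 1 fit of edgeR 4.0.16 with a term per group, after filterByExpr and TMM scaling, under R 4.3.3. The robust quasi-likelihood F test was used with Benjamini-Hochberg adjustment over the 14599, 13356 or 13799 genes tested, and a threshold of 0.05. The residual degrees of freedom were 6, 3 and 4. The mean of the del-cIDR clones was a contrast with equal weight for each clone. Fold changes are on the log2 scale with a prior count of 0.125, and log CPM for the list tests and ES cells with 2. Standard errors come from the weights of the fitted means and the quasi-likelihood variance. A gene with 0 counts in every library of a group is given as a bound against a floor of 3 counts over the group. The floor covers counting error only.

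Gene lists were fixed, like the comparisons, tests and alternatives, before the data were examined. For THP-1 cells they were HOX-MEIS self-renewal, monocyte-macrophage, granule, interferon response, NF-kB inflammatory, MHC class II, adhesion and matrix, cell cycle, growth arrest and apoptosis, nucleolar and MYC targets, COMPASS and Polycomb, stress and immediate early, mitochondrial encoded, and other cell types. For mouse cells they were naive pluripotency, formative and primed, primitive streak and mesendoderm, mesoderm and cardiac, blood and endothelium, endoderm, neuroectoderm, Hox, trophoblast, germ line and 2-cell like, fibroblast, cell cycle, hypoxia and glycolysis, and COMPASS and Polycomb. Each but the mitochondrial one was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over a comparison's lists. Where a list passed at the preset correlation, it also passed with an estimated correlation unless that p is given beside it. A sentence on a list gives the members past the threshold over all genes, the number that passed when adjusted over the list alone, the median log2 fold change and the adjusted p.

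Genes were named by a rule. KDM6A came first, with EIF4G1, EIF4G2 and EIF4G3 as a check of the labels. Then came the genes with the largest change up and down among those past the threshold, with a mean of at least 1 CPM, counts scaled to library size, and moved the same way in every pair of libraries. The number was 10 each way for WT against Vector, WT against del-cIDR, UTX-KO against WT and del-cIDR against WT, and 5 each way otherwise. Members of the fixed lists with the largest change in the comparison described were the last part. A few genes that the rule picks are not reported here. Genes whose reads overlap a neighbour, paralog or readthrough transcript are called uncertain.

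Overlap between comparisons that share a control was simulated with 20 draws of data without an effect. Few genes are called in such data, so simulated counts of shared calls were bound to be near 0. Recovery was tested on counts drawn from the fitted model, with known changes put into 67, 67 and 66 genes. The rates hold only as far as that model does. In WT against Vector 73.1%, 83.6% and 97.0% of genes changed by a log2 of 0.5, 1 and 2 were called, with 6.63% false calls. In batch2 the shares were 37.3%, 80.6% and 90.9% (7.95% false), and in embryoid bodies 68.7%, 85.1% and 97.0% (5.11% false).

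Peaks and loops on the autosomes and X were used, and peaks overlapped if they shared at least 1 base. As background, peaks were moved by 1 Mb. The gene annotation gave no strand, so both ends of a gene were used, with windows of 2.5 kb and 50 kb. Of the tested genes 13975 of 14585 (95.8%) matched the annotation for the first set and 12849 of 13345 (96.3%) for batch2. Peak counts near changed genes were compared by Fisher's exact test and loop counts by a permutation test with 100000 draws among genes of like expression. For ES cells, medians of lists were ranked among 10000 random lists. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 was used for peaks, loops and plots.

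Alternatives tried were the DESeq2 1.42.0 test on the same counts, its size factors in the edgeR fit, no expression filter, only the libraries compared, the replicate number as a block, leaving out each library in turn, each clone alone, an estimated correlation and fry for the lists, stricter peaks, loops and overlaps, other windows, and a prior count of 0.5 for ES cells. Added after seeing the data were fits of batch2 without RNR1, RNR2 and TALAM1. Batch and construct are separate in THP-1 RNA-seq, since each set has its own Vector libraries, and the sets were joined in 1 fit only to test their difference. Human lists of ATF4 targets, hypoxia and cholesterol synthesis and a mouse list of imprinted genes were added after seeing the data for the closing observations. The deposited TPM and FPKM values, per the file headers, were left out, since the tests need counts.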

Results

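The series measured what the histone H3K27 demethylase UTX, encoded by KDM6A, does in THP-1 cells, a human monocytic leukaemia line, and in mouse embryonic stem (ES) cells and the embryoid bodies grown from them. THP-1 cells carried empty vector, wild-type UTX (WT), UTX without its core intrinsically disordered region (del-cIDR), UTX chimeras labelled eIFIDR and FUSIDR, in which a foreign disordered region stands in for the lost one, or UTX without its tetratricopeptide repeats (del-TPR). RNA-seq covered these 6 groups with 2 libraries each, at 15322765 to 30868454 counts per library. A second THP-1 set, batch2, held Vector, WT and MT2, a construct undefined by the labels, with 2 libraries each. Its Vector libraries held 4073458 and 3258992 counts, WT 8898454 and 8352171, and MT2 7755562 and 6120207. Mouse embryoid bodies were WT, UTX-KO and del-cIDR clone3 and clone72, with 2 libraries each of 4240580 to 10326198 counts, and ES cells had 1 library per genotype of 8705286 to 12611891 counts. THP-1 cells were also profiled by PRO-seq, which maps transcribing polymerase (2 lists for each of Vector, WT and del-cIDR), by ChIP-seq for UTX, the methyltransferase MLL4 and 5 histone marks (1 list per group), and by HiChIP, which lists chromatin contacts at H3K4me3 or H3K27ac. The read depth behind the peak and loop lists is unknown.

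In the batch2 Vector libraries the mitochondrial ribosomal RNA RNR2 took 42.3% and 42.9% of all counts, against 5.61% and 5.62% in WT and 0.767% to 1.07% in the first set. TALAM1, the antisense RNA of MALAT1, took 4.64% and 4.60% there, against 0.386% and 0.390% in WT. These shares stand beside every batch2 comparison with Vector. Libraries of 1 group differed little beyond counting error in all 3 sets, with a variance of 1.11 to 2.24 times that of counting alone. The labels name 1 line per construct, so the tests compare these cultures. Values below are log2 fold changes ± the standard error of the fit with n = 2 libraries per group, unless a fold is named, and p-values are adjusted.

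KDM6A itself was near background in first-set Vector, at 1.03 ± 0.213 CPM (SD, n = 2), and at 110 ± 3.68 in WT, 162 ± 2.33 in del-cIDR, 203 ± 2.62 in eIFIDR, 304 ± 2.83 in FUSIDR and 318 ± 4.17 in del-TPR. Batch2 differed: KDM6A stood at 25.4 ± 1.73 in Vector, 64.5 ± 1.26 in WT and 54.5 ± 0.262 in MT2. The translation factor EIF4G1 did not pass the test in eIFIDR against Vector (-0.01, adjusted p = 0.594). Of its relatives, EIF4G2 (-0.16 ± 0.0183) fell and EIF4G3 (0.12 ± 0.0277) rose in eIFIDR. In embryoid bodies Kdm6a was at 80.9 ± 1.75 CPM in WT, 35.1 ± 7.34 in UTX-KO, 89.0 ± 0.983 in clone3 and 85.4 ± 0.545 in clone72. Transcript thus remained in UTX-KO, and the counts do not separate full-length from truncated transcripts.

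Wild-type UTX against Vector asks what re-expression of UTX changes in THP-1 cells. Genes of the interferon and chemokine response rose, among them IDO1 (3.09 ± 0.309), which degrades tryptophan, the monocyte attractants CCL8 (3.01 ± 0.232) and CCL2 (2.42 ± 0.0741), the interferon-induced IFI44L (2.69 ± 0.0662), and TNFAIP6 (2.35 ± 0.337), which binds hyaluronan. Also higher were the matrix oxidase LOXL4 (3.19 ± 0.356), the adhesion receptor CD48 (2.99 ± 0.53), the actin-binding CORO2B (2.43 ± 0.26) and the secreted galectin ligand LGALS3BP (2.35 ± 0.0628). Falls were seen in the hormone STC1 (-4.21 ± 0.8), the Rab regulator TBC1D30 (-2.87 ± 0.0981) and the kinase PNCK (-2.87 ± 0.126). The glycolytic enzymes ENO2 (-2.59 ± 0.239) and ALDOC (-2.30 ± 0.107), the vasodilator ADM (-2.55 ± 0.349) and the oxygen sensor EGLN3 (-2.27 ± 0.522) fell too. So did SULF2 (-2.51 ± 0.147), an editor of heparan sulfate, the eosinophil granule protein PRG2 (-2.17 ± 0.136) and the tight junction protein CLDN10 (-2.02 ± 0.295). Of 14599 genes tested, 3533 rose and 2377 fell, 199 and 178 of them by at least 2-fold, though 3146 rose and 2855 fell when scaled with only the libraries compared.

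In the fixed list of interferon response genes 30 of 30 measured genes rose and 0 fell, 30 adjusted over the list alone, with a median of 1.60 (adjusted p = 8.32e-29). The antiviral MX1 (2.09 ± 0.0506), IFI44 (2.10 ± 0.0702) and IFI6 (2.02 ± 0.0288) were also higher, after IFI44L. In the NF-kB inflammatory list 15 of 23 measured genes rose and 0 fell, 16 adjusted over the list alone, with a median of 0.49 (adjusted p = 2.56e-09). Examples were the chemokine CXCL10 (2.07 ± 0.0925) and the adhesion molecule ICAM1 (1.58 ± 0.0648). In the monocyte-macrophage list 27 of 40 measured genes rose and 6 fell, 36 adjusted over the list alone, with a median of 0.30 (adjusted p = 2.56e-07). Here the complement genes C1QB (1.34 ± 0.365) and C1QA (1.33 ± 0.152) rose while the lectin FCN1 (-3.15 ± 1.22) and the receptor TREM1 (-1.33 ± 0.19) fell. Stress and immediate early genes gave 10 up and 2 down of 17, 12 adjusted over the list alone, median 0.20, adjusted p = 0.00917, or adjusted p = 0.0794 with an estimated correlation, with FOSB (1.07 ± 0.286) and FOS (0.86 ± 0.0333) higher. For MHC class II the result was 4 up and 0 down of 6, 5 adjusted over the list alone, median 0.32, adjusted p = 0.0156, or adjusted p = 0.0794 with an estimated correlation, with the protease CTSS (0.71 ± 0.0266) up. Nucleolar and MYC targets, with RRP9 (0.38 ± 0.0469) up and the lactate dehydrogenase LDHA (-0.44 ± 0.0192) down, gave 11 up and 2 down of 20, 13 adjusted over the list alone, median 0.11, adjusted p = 0.0395, or adjusted p = 0.116 with an estimated correlation. For the cell cycle list, with MKI67 (-0.41 ± 0.0228) down and CDC20 (0.33 ± 0.0199) up, the values were 4 up and 13 down of 32, 18 adjusted over the list alone, median -0.03, adjusted p = 0.0424, or adjusted p = 0.116 with an estimated correlation. COMPASS and Polycomb genes, with the H3K27 demethylase KDM6B (-0.69 ± 0.103) and the Polycomb factor JARID2 (-0.52 ± 0.0585) down, gave 3 up and 9 down of 21, 14 adjusted over the list alone, median -0.09, adjusted p = 0.0395, or adjusted p = 0.176 with an estimated correlation.

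The other lists did not pass the set test in WT against Vector. Adhesion and matrix genes went both ways, with VCAM1 (4.42 ± 0.852) and the integrin ITGB8 (1.93 ± 0.583) up and fibronectin FN1 (-1.82 ± 0.122) down (15 up and 8 down of 37, 27 adjusted over the list alone, median 0.11, adjusted p = 0.214). The HOX-MEIS self-renewal list, which held HOXA6 (-2.03 ± 0.64) and the survival gene BCL2 (-0.55 ± 0.0331) among its falls, gave 3 up and 10 down of 23, 13 adjusted over the list alone, median -0.10, adjusted p = 0.0769. Granule genes, with myeloperoxidase MPO (-0.83 ± 0.0854) and the granulocyte regulator CEBPE (-0.66 ± 0.156) down, gave 1 up and 3 down of 7, 4 adjusted over the list alone, median -0.15, adjusted p = 0.254. Growth arrest and apoptosis genes, with BTG2 (0.73 ± 0.0512) up, gave 6 up and 4 down of 22, 10 adjusted over the list alone, median 0.04, adjusted p = 0.75. Markers of other cell types gave 1 up and 1 down of 4, 2 adjusted over the list alone, median 0.12, adjusted p = 0.762, with the B cell gene PAX5 (1.05 ± 0.151) up. The list of 13 mitochondrial genes was not analysed. DESeq2 called 3343 genes in all, against 5910 by edgeR.

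**Figure D1:**
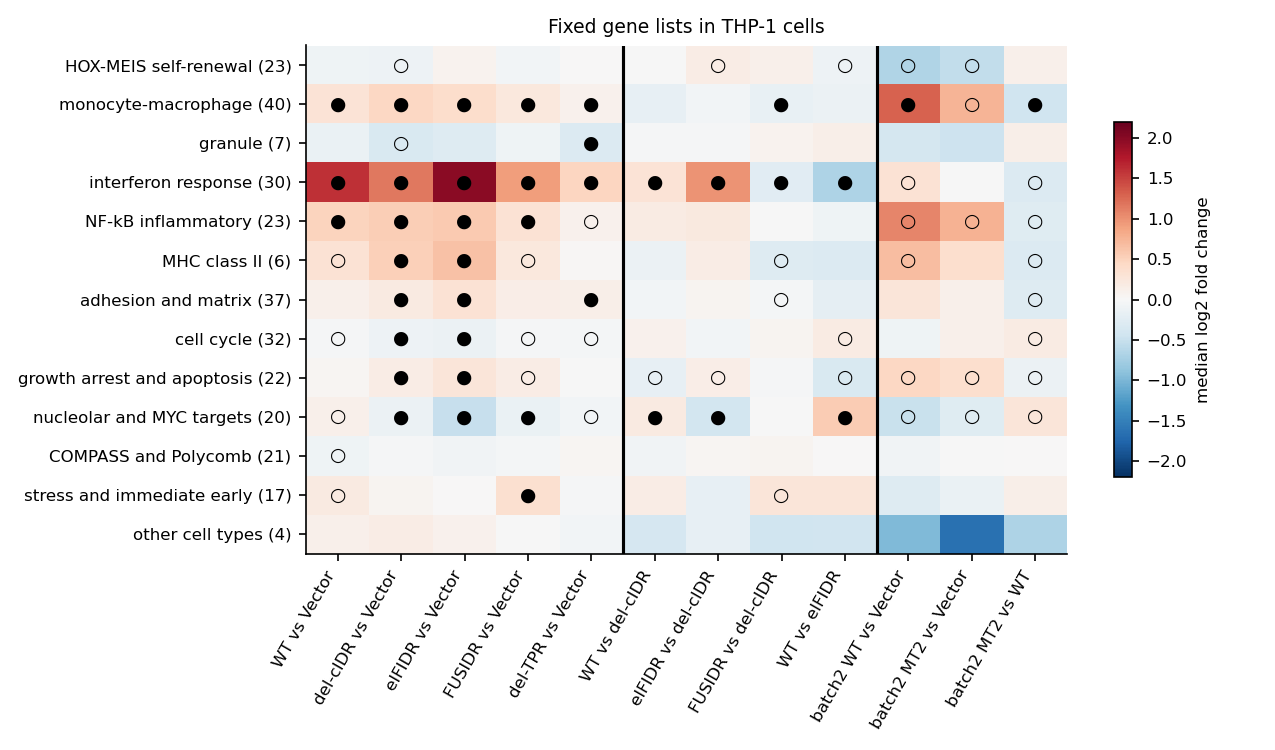
Median log2 fold change of each fixed gene list (vertical) in each comparison of THP-1 cells (horizontal), with the number of genes measured in the first set in brackets. Filled dots pass an adjusted p of 0.05 with the preset and the estimated correlation, open dots with the preset one alone, and the interferon response list is highest in eIFIDR against Vector, at 1.98.

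Against Vector, del-cIDR asks what UTX does without the disordered region. It also raised CCL8 (2.92 ± 0.233), TNFAIP6 (2.63 ± 0.335), IDO1 (2.57 ± 0.317) and the myeloid receptor CD300E (2.50 ± 0.248). The eosinophil gene PRG2 (-2.14 ± 0.138), the IgG-binding mucin-like FCGBP (-1.83 ± 0.274), the energy balance peptide ENHO (-1.75 ± 0.397) and the prolactin receptor PRLR (-1.45 ± 0.273) fell. PCDHGC5 (-2.04 ± 0.513) also fell, but it shares its last exons with its gene cluster, so its count is uncertain. In the interferon response list 30 of 30 measured genes rose and 0 fell, 30 adjusted over the list alone, with a median of 1.16 (adjusted p = 7.77e-37). Examples were IFI44L (2.21 ± 0.0679) and MX1 (1.82 ± 0.0516). In the monocyte-macrophage list 30 of 40 measured genes rose and 3 fell, 34 adjusted over the list alone, with a median of 0.45 (adjusted p = 4.93e-15). The gelatinase MMP9 (2.23 ± 0.0395), the inhibitory receptor FCGR2B (1.48 ± 0.131) and the endotoxin co-receptor CD14 (1.05 ± 0.0543) were high in that list. In all, 1974 genes rose and 2079 fell, 217 and 40 of them by at least 2-fold. DESeq2 called 2001, of which 60.4% rose, against 48.7% by edgeR.

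Further lists passed in del-cIDR. NF-kB genes rose, including CCL2 (2.17 ± 0.0753) and ICAM1 (1.41 ± 0.066) (15 up and 0 down of 23, 17 adjusted over the list alone, median 0.55, adjusted p = 1.52e-12). MHC class II genes rose with their master regulator CIITA (1.22 ± 0.145) (5 up and 0 down of 6, 5 adjusted over the list alone, median 0.53, adjusted p = 8.13e-06). Adhesion and matrix genes rose with VCAM1 (4.06 ± 0.857) (16 up and 3 down of 37, 20 adjusted over the list alone, median 0.20, adjusted p = 0.000106), and growth arrest genes with the cyclin kinase inhibitor CDKN1A (0.92 ± 0.0369) (11 up and 1 down of 22, 14 adjusted over the list alone, median 0.17, adjusted p = 0.00033). Cell cycle genes fell slightly, for example the mitotic cyclin CCNB2 (-0.23 ± 0.0328) (1 up and 20 down of 32, 23 adjusted over the list alone, median -0.10, adjusted p = 7.72e-07). Nucleolar and MYC targets fell too, for example ODC1 (-0.23 ± 0.0236), the first enzyme of polyamine synthesis, and the pyrimidine synthesis enzyme CAD (-0.20 ± 0.0331) (0 up and 14 down of 20, 14 adjusted over the list alone, median -0.13, adjusted p = 1.26e-05). The HOX-MEIS list gave 1 up and 9 down of 23, 12 adjusted over the list alone, median -0.11, adjusted p = 0.0306, or adjusted p = 0.0681 with an estimated correlation.

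WT against del-cIDR asks what the disordered region adds. Oxygen-responsive and glycolytic genes were far lower in WT: STC1 (-5.48 ± 0.788), ENO2 (-3.17 ± 0.233), ADM (-2.97 ± 0.342), EGLN3 (-3.14 ± 0.501) and ALDOC (-2.44 ± 0.106). The kinase PNCK (-3.20 ± 0.125), TBC1D30 (-3.16 ± 0.0969), the heparan sulfate editor SULF2 (-2.86 ± 0.144), the glycan enzyme MGAT3 (-2.70 ± 0.2) and the elongation factor TCEA3 (-2.25 ± 0.257) were lower as well. Higher in WT were CORO2B (3.04 ± 0.303), LOXL4 (2.11 ± 0.262), the Rap regulator SIPA1L2 (1.75 ± 0.139), the potassium channel KCNJ2 (1.52 ± 0.15), ENHO (1.5 ± 0.401), the immediate early FOSB (1.46 ± 0.308) and the anthrax toxin receptor ANTXR1 (1.42 ± 0.0649). UTP14C (2.45 ± 0.629), CD302 (1.51 ± 0.272) and PCDHGC5 (2.04 ± 0.509) were higher too, but their reads overlap a paralog, a readthrough partner or a shared exon, which leaves their counts uncertain. In the interferon response list 25 of 30 measured genes rose and 0 fell, 25 adjusted over the list alone, with a median of 0.30 (adjusted p = 1.78e-08). Examples were the ubiquitin-like ISG15 (0.86 ± 0.0409), IFIT1 (0.52 ± 0.0574) and IFI35 (0.48 ± 0.0489). In the nucleolar and MYC list 19 of 20 measured genes rose and 1 fell, 20 adjusted over the list alone, with a median of 0.20 (adjusted p = 3.48e-06). Here ODC1 (0.44 ± 0.0232) and RRP9 (0.43 ± 0.0469) were higher and LDHA (-0.48 ± 0.0192) lower. The monocyte-macrophage list split and did not pass, with FCGR2B (-1.98 ± 0.143) and TREM1 (-1.78 ± 0.183) down and C1QB (1.31 ± 0.359) up (15 up and 19 down of 40, 36 adjusted over the list alone, median -0.19, adjusted p = 0.06). Growth arrest genes, with CDKN1A (-0.60 ± 0.0347) down, gave 3 up and 11 down of 22, 15 adjusted over the list alone, median -0.18, adjusted p = 0.0187, or adjusted p = 0.15 with an estimated correlation. Over all genes 3838 were higher and 2527 lower in WT, 62 and 259 of them by at least 2-fold, and DESeq2 called 3687. The excess of rises depended on scaling: with only the libraries compared the split was 3268 and 3008. KDM6A (-0.56 ± 0.0303) was lower in WT too, so its level and the line are confounded with the deletion.

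The chimeras ask whether a foreign disordered region stands in for the lost one. In eIFIDR against Vector, genes of the amino acid response rose: ASNS (3.98 ± 0.0791), which makes asparagine, CHAC1 (3.95 ± 0.109), which degrades glutathione, and STC2 (3.74 ± 0.114), next to the spectrin SPTB (3.90 ± 0.293). FCGBP (-2.37 ± 0.298) and PRG2 (-2.30 ± 0.137) fell, as did HYPK (-2.99 ± 0.496), CD302 (-2.75 ± 0.438) and MYCBP (-2.59 ± 1.03), which overlap readthrough transcripts and are uncertain. In the interferon response list 30 of 30 measured genes rose and 0 fell, 30 adjusted over the list alone, with a median of 1.98 (adjusted p = 2.97e-24). Among its members were IFI44L (3.34 ± 0.0647), MX1 (2.92 ± 0.0488), the regulator IRF7 (2.90 ± 0.368) and the antiviral RSAD2 (2.88 ± 0.0936). In the nucleolar and MYC list 0 of 20 measured genes rose and 20 fell, 20 adjusted over the list alone, with a median of -0.52 (adjusted p = 3.74e-11). Examples were the ribosome assembly factors MRTO4 (-0.81 ± 0.0316), NOP16 (-0.79 ± 0.0491) and GNL3 (-0.69 ± 0.0297). Cell cycle genes fell, for example CCNE1 (-0.60 ± 0.0514) and GINS2 (-0.56 ± 0.0489) (3 up and 25 down of 32, 29 adjusted over the list alone, median -0.14, adjusted p = 2.17e-05), and growth arrest genes rose with SESN2 (2.61 ± 0.0716) and BBC3 (0.97 ± 0.104) (17 up and 1 down of 22, 18 adjusted over the list alone, median 0.27, adjusted p = 2.17e-05). The NF-kB list rose with CCL2 (2.50 ± 0.0735) and CXCL10 (2.43 ± 0.0905) (18 up and 2 down of 23, 21 adjusted over the list alone, median 0.57, adjusted p = 1.66e-06), the MHC class II list with HLA-DQA1 (1.69 ± 0.512) (6 up and 0 down of 6, 6 adjusted over the list alone, median 0.64, adjusted p = 0.000484) and the adhesion list with VCAM1 (4.41 ± 0.851) (22 up and 4 down of 37, 27 adjusted over the list alone, median 0.32, adjusted p = 0.0015). Monocyte-macrophage genes gave 27 up and 9 down of 40, 36 adjusted over the list alone, median 0.39, adjusted p = 0.000128, with MMP9 (1.65 ± 0.0402) up and FCN1 (-2.02 ± 0.839) down. In all 4084 genes rose and 4196 fell, 651 and 132 by at least 2-fold.

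In FUSIDR against Vector, CD48 (2.91 ± 0.539), the immediate early regulator EGR3 (2.89 ± 0.327), CHAC1 (2.88 ± 0.114) and IDO1 (2.84 ± 0.317) rose, and FN1 (-1.91 ± 0.137), the receptor GPRC5B (-1.65 ± 0.371), PRG2 (-1.58 ± 0.13), PNCK (-1.57 ± 0.0998) and ADM (-1.56 ± 0.299) fell. In the interferon response list 30 of 30 measured genes rose and 0 fell, 30 adjusted over the list alone, with a median of 0.92 (adjusted p = 8.61e-27). Examples were IFI44L (1.44 ± 0.0732), IRF7 (1.35 ± 0.417) and MX1 (1.33 ± 0.0548). NF-kB genes rose with CXCL10 (1.49 ± 0.0991) and ICAM1 (1.47 ± 0.0673) (15 up and 0 down of 23, 15 adjusted over the list alone, median 0.31, adjusted p = 2.85e-09). Monocyte-macrophage genes, with MMP9 (1.19 ± 0.043) up and the proteoglycan VCAN (-1.14 ± 0.0456) down, gave 21 up and 5 down of 40, 28 adjusted over the list alone, median 0.23, adjusted p = 0.000137. Stress and immediate early genes rose, among them FOSB (1.61 ± 0.283), ASNS (1.56 ± 0.0895) and EGR1 (1.39 ± 0.0489) (11 up and 4 down of 17, 16 adjusted over the list alone, median 0.36, adjusted p = 0.00143). Nucleolar and MYC targets fell, for example LDHA (-0.39 ± 0.0194) and the nucleolar methyltransferase FBL (-0.28 ± 0.0269) (0 up and 13 down of 20, 15 adjusted over the list alone, median -0.14, adjusted p = 6.69e-06). Growth arrest genes, with SESN2 (1.75 ± 0.0768) up, gave 11 up and 2 down of 22, 13 adjusted over the list alone, median 0.16, adjusted p = 0.00302, or adjusted p = 0.0574 with an estimated correlation. The MHC class II list gave 5 up and 0 down of 6, 5 adjusted over the list alone, median 0.24, adjusted p = 0.00626, or adjusted p = 0.0517 with an estimated correlation and the cell cycle list 4 up and 10 down of 32, 14 adjusted over the list alone, median -0.03, adjusted p = 0.0212, or adjusted p = 0.0705 with an estimated correlation. In all 2410 genes rose and 2350 fell, 230 and 70 by at least 2-fold, and DESeq2 called 2623.

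Against del-cIDR the 2 chimeras moved interferon genes in opposite directions. In eIFIDR against del-cIDR 29 of 30 measured genes rose and 0 fell, 29 adjusted over the list alone, with a median of 0.98 (adjusted p = 3.63e-20) in that list. Examples were RSAD2 (1.39 ± 0.0659), IFIT1 (1.31 ± 0.0535) and OAS2 (1.21 ± 0.0261). In FUSIDR against del-cIDR 2 of 30 measured genes rose and 19 fell, 22 adjusted over the list alone, with a median of -0.26 (adjusted p = 6.69e-07). Examples were IFI6 (-0.87 ± 0.0276), IFI44 (-0.80 ± 0.0617) and IFI44L (-0.76 ± 0.0528). Rises in eIFIDR included ASNS (4.35 ± 0.0871), SPTB (3.66 ± 0.27), CHAC1 (3.37 ± 0.0919), the peptide ADM2 (3.18 ± 0.095) and the immune ligand ULBP1 (2.99 ± 0.167). Its falls included FAM135B (-1.88 ± 0.362), CTXN1 (-1.51 ± 0.207), the IgG receptor FCGR3A (-1.32 ± 0.159), and the uncertain HYPK (-2.78 ± 0.5) and CD302 (-1.96 ± 0.458). In FUSIDR EGR3 (3.20 ± 0.352), CHAC1 (2.30 ± 0.0977) and FOSB (2.00 ± 0.305) rose, as did the uncertain PCDHGC5 (2.76 ± 0.5) and PLA2G4B (2.33 ± 0.621), while ADM (-1.98 ± 0.291), ENO2 (-1.92 ± 0.185), PNCK (-1.90 ± 0.0976), the chaperone CLU (-1.89 ± 0.174) and MGAT3 (-1.88 ± 0.179) fell. Nucleolar and MYC targets were lower in eIFIDR, with MRTO4 (-0.68 ± 0.0319) and PPAN (-0.63 ± 0.0587) (0 up and 20 down of 20, 20 adjusted over the list alone, median -0.40, adjusted p = 2.55e-11). Monocyte-macrophage genes were lower in FUSIDR, with FCGR2B (-1.25 ± 0.132), TREM1 (-1.18 ± 0.174) and MMP9 (-1.04 ± 0.0335) (2 up and 23 down of 40, 25 adjusted over the list alone, median -0.17, adjusted p = 2.97e-07). Calls numbered 3492 up and 3660 down for eIFIDR against del-cIDR and 2136 up and 2055 down for FUSIDR, and DESeq2 called 4747 and 2068 in all.

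WT and eIFIDR also differed directly. Lower in WT were STC1 (-4.70 ± 0.792), STC2 (-4.37 ± 0.132), ULBP1 (-4.22 ± 0.233), ASNS (-3.97 ± 0.0763) and SPTB (-3.71 ± 0.268), and higher were the potassium channel KCNK13 (2.58 ± 0.45), EGR3 (2.10 ± 0.48), FOSB (2.10 ± 0.342) and the uncertain CD302 (3.47 ± 0.425) and HYPK (3.27 ± 0.489). In the interferon response list 3 of 30 measured genes rose and 27 fell, 30 adjusted over the list alone, with a median of -0.67 (adjusted p = 1.46e-09). Its members IRF7 (-1.12 ± 0.236) and RSAD2 (-1.09 ± 0.0616) were lower in WT. In the nucleolar and MYC list 19 of 20 measured genes rose and 0 fell, 19 adjusted over the list alone, with a median of 0.56 (adjusted p = 7.72e-10). Its members MRTO4 (1.07 ± 0.0307) and NOP16 (0.96 ± 0.0478) were higher in WT. Over all genes 4644 were higher and 4315 lower in WT, 126 and 616 by at least 2-fold.

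UTX without its tetratricopeptide repeats, which in UTX bind partner proteins, changed 3142 genes against Vector. PAX5 (1.27 ± 0.143), a B cell regulator, NKX2-2 (1.24 ± 0.33), PNMA2 (1.22 ± 0.169) and IDO1 (1.19 ± 0.333) rose. LOC101929592 (-0.88 ± 0.197), CIB3 (-0.84 ± 0.243), PRG2 (-0.82 ± 0.0976) and the uncertain BCAP29 (-0.89 ± 0.19) and HYPK (-1.52 ± 0.332) fell. In the interferon response list 29 of 30 measured genes rose and 0 fell, 29 adjusted over the list alone, with a median of 0.48 (adjusted p = 3.58e-27). Examples were IFI44L (1.09 ± 0.0703), MX1 (0.76 ± 0.0535) and RSAD2 (0.75 ± 0.103). Adhesion and matrix genes rose with the integrin ITGA1 (1.17 ± 0.281) (15 up and 1 down of 37, 18 adjusted over the list alone, median 0.13, adjusted p = 8.69e-05), and monocyte-macrophage genes with FCGR2B (0.61 ± 0.134) (16 up and 5 down of 40, 27 adjusted over the list alone, median 0.10, adjusted p = 0.000767). Granule genes fell with RNASE2 (-0.40 ± 0.0196), CTSG (-0.36 ± 0.024) and MPO (-0.30 ± 0.0739) (0 up and 3 down of 7, 3 adjusted over the list alone, median -0.30, adjusted p = 0.00191). Nucleolar and MYC targets gave 0 up and 8 down of 20, 11 adjusted over the list alone, median -0.06, adjusted p = 0.0169, or adjusted p = 0.0695 with an estimated correlation. In all 1533 genes rose and 1609 fell, 42 and 22 by at least 2-fold. DESeq2 called 1322, of which 2 by at least 2-fold, and 1771 were called without Vector replicate 1 and 1983 without del-TPR replicate 2.

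**Figure D2:**
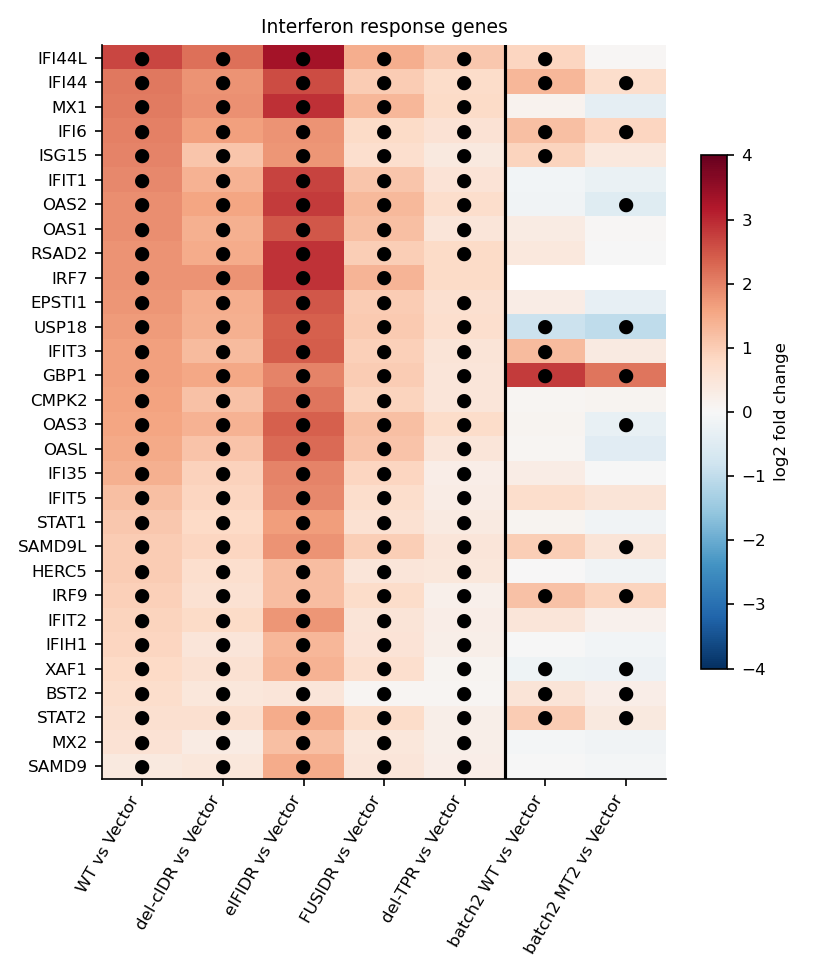
Log2 fold changes against Vector of the interferon response genes (vertical) in each THP-1 construct of both sets (horizontal), with a dot on genes past an adjusted p of 0.05 and IRF7 left blank in batch2, where it was not tested. All 30 genes are past the threshold in the first-set WT, del-cIDR, eIFIDR and FUSIDR columns, 29 in del-TPR.

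The comparisons with Vector share its 2 libraries, so their calls overlap in part for that reason. WT and del-cIDR both raised 1086 genes (477.7 if independent) and both lowered 673 (338.5), while 634 went opposite ways. Simulated data with shared Vector libraries and no effect gave 0 and 0.05. The covariance of the fold changes was 0.0861, against 0.0322 in the simulation, a difference of 0.054. eIFIDR and FUSIDR shared 1879 rises and 1887 falls (674.2 and 675.4 if independent; simulated 0.05 and 0.1), with a covariance difference of 0.143, and 171 went opposite ways. WT and del-TPR shared 620 and 288 (371 and 262; simulated 0.15 and 0.05), with a difference of 0.0232, while 909 went opposite ways. The 2 Vector libraries were too few to split, so part of each excess may come from shared controls.

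In batch2, WT against Vector sets 64.5 CPM of KDM6A against 25.4. CD163 (5.17 ± 1.41), the haemoglobin scavenger receptor of macrophages, TREM1 (4.39 ± 0.832), C1QA (4.36 ± 0.993) and the calgranulin S100A12 (4.05 ± 0.255) rose. Against 0 counts in Vector, and a floor of 3 counts over the group, the glucan receptor CLEC7A was at least 10.7-fold higher in WT and the ubiquitin ligase MARCHF1 at least 9.71-fold. KTI12, NPIPA1 and ZNF816-ZNF321P were at least 30.7-fold, 15.6-fold and 5.75-fold higher. Against 0 counts in WT, CADPS2 was at least 28.8-fold lower, and SNURF, ARPIN-AP3S2 and BLOC1S5 at least 108-fold, 106-fold and 73.7-fold. ZNF660-ZNF197 (-8.11 ± 4.6) fell as well. Of these, KTI12, NPIPA1, SNURF, BLOC1S5 and the hyphenated readthrough genes share reads with paralogs or neighbours and are uncertain. In all 3112 genes rose and 3284 fell, 1050 and 981 by at least 2-fold.

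In the monocyte-macrophage list of batch2 WT 34 of 38 measured genes rose and 1 fell, 35 adjusted over the list alone, with a median of 1.30 (adjusted p = 3.76e-13). NF-kB genes rose with the neutrophil attractants CXCL2 (2.96 ± 0.82), CXCL8 (2.93 ± 0.147) and CXCL1 (2.54 ± 0.722) (14 up and 0 down of 22, 15 adjusted over the list alone, median 1.07, adjusted p = 0.00019, or adjusted p = 0.109 with an estimated correlation). Interferon response genes, with GBP1 (2.81 ± 0.835) and IFI44 (1.33 ± 0.133) up, gave 10 up and 2 down of 29, 12 adjusted over the list alone, median 0.31, adjusted p = 0.00206, or adjusted p = 0.184 with an estimated correlation. HOX-MEIS genes, with SOX4 (-2.15 ± 0.0927) and MEF2C (-1.49 ± 0.0754) down, gave 2 up and 12 down of 19, 15 adjusted over the list alone, median -0.67, adjusted p = 0.00179, or adjusted p = 0.109 with an estimated correlation. Nucleolar genes, with NOP58 (-2.18 ± 0.0506) down, gave 0 up and 14 down of 20, 14 adjusted over the list alone, median -0.49, adjusted p = 0.000121, or adjusted p = 0.109 with an estimated correlation, and growth arrest genes, with TNFRSF10B (1.67 ± 0.124) and CDKN1A (1.08 ± 0.137) up, gave 9 up and 0 down of 22, 9 adjusted over the list alone, median 0.45, adjusted p = 0.00257, or adjusted p = 0.109 with an estimated correlation. MHC class II gave 4 up and 0 down of 7, 5 adjusted over the list alone, median 0.68, adjusted p = 0.0247, or adjusted p = 0.226 with an estimated correlation. Granule genes did not pass the set test, with CTSG (-1.96 ± 0.0374) and MPO (-1.51 ± 0.208) down (0 up and 3 down of 6, 3 adjusted over the list alone, median -0.38, adjusted p = 0.0522).

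In MT2 against Vector, CD163 (4.55 ± 1.41), C1QA (3.99 ± 0.996), TREM1 (3.82 ± 0.836) and CXCL1 (2.92 ± 0.722) rose and SOX4 (-1.98 ± 0.0949) fell. MARCHF1, CLEC7A and ANKS1B were at least 7.34-fold, 6.44-fold and 4.95-fold higher against 0 counts in Vector, and NPIPA1 and ZNF816-ZNF321P at least 25.7-fold and 3.51-fold. The uncertain GIMAP5, ARPIN-AP3S2, ERVK3-1 and TGIF2-RAB5IF were at least 26-fold, 83.7-fold, 61.5-fold and 22.4-fold lower. MYCBP (-4.81 ± 0.57), also uncertain, was lower too. In the monocyte-macrophage list 28 of 38 measured genes rose and 2 fell, 30 adjusted over the list alone, with a median of 0.74 (adjusted p = 8.46e-09, and adjusted p = 0.0658 with an estimated correlation). Interferon response genes did not pass, with a median below 0 and a mean of 0.12 (7 up and 4 down of 29, 11 adjusted over the list alone, median -0.01, adjusted p = 0.629). NF-kB genes gave 10 up and 0 down of 22, 11 adjusted over the list alone, median 0.77, adjusted p = 0.00388, or adjusted p = 0.149 with an estimated correlation, and HOX-MEIS genes 2 up and 9 down of 19, 11 adjusted over the list alone, median -0.53, adjusted p = 0.00388, or adjusted p = 0.149 with an estimated correlation. In all 2772 genes rose and 2952 fell, 798 and 811 by at least 2-fold. WT and MT2 shared 2237 rises and 2478 falls (645.9 and 725.8 if independent; simulated 0.1 and 0.1), with a covariance difference of 0.704.

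MT2 against WT, a comparison that does not use the Vector libraries, gave 1793 genes higher and 1811 lower in MT2, 82 and 104 by at least 2-fold. In the monocyte-macrophage list 1 of 38 measured genes rose and 32 fell, 34 adjusted over the list alone, with a median of -0.44 (adjusted p = 1.05e-13). FCGR2B (-0.78 ± 0.0866) and the integrin ITGAM (-0.76 ± 0.0532) were lower in MT2. Interferon genes were lower in MT2, with IFIT3 (-0.89 ± 0.125) and IFI44L (-0.81 ± 0.0738) (0 up and 18 down of 29, 18 adjusted over the list alone, median -0.30, adjusted p = 1.98e-08, or adjusted p = 0.0786 with an estimated correlation). NF-kB genes gave 1 up and 8 down of 22, 10 adjusted over the list alone, median -0.28, adjusted p = 0.00223, or adjusted p = 0.0786 with an estimated correlation, and adhesion and matrix genes 2 up and 15 down of 32, 18 adjusted over the list alone, median -0.29, adjusted p = 0.000367, or adjusted p = 0.0786 with an estimated correlation. Cell cycle genes, with the topoisomerase TOP2A (0.56 ± 0.0369) up, gave 16 up and 1 down of 32, 19 adjusted over the list alone, median 0.19, adjusted p = 0.000131, or adjusted p = 0.0786 with an estimated correlation, and nucleolar genes, with NOP58 (0.69 ± 0.0482) up, gave 13 up and 1 down of 20, 15 adjusted over the list alone, median 0.26, adjusted p = 2.55e-05, or adjusted p = 0.0786 with an estimated correlation. IFT80, a ciliary transport gene, was at least 15.7-fold higher, and SNX15 and GIMAP5 at least 22.2-fold and 11.8-fold lower, all uncertain. NT5C1B-RDH14, BLOC1S5 and SNURF were at least 21.5-fold, 15-fold and 8.07-fold higher, KTI12 and ERVK3-1 at least 124-fold and 16.3-fold lower, ZNF660-ZNF197 (8.5 ± 4.58) up and URGCP-MRPS24 (-4.90 ± 1.2) down, all of them uncertain. KDM6A was slightly lower in MT2 (-0.24, adjusted p = 0.00533). DESeq2 called 1739, and 2349 and 2373 were called without WT replicate 1 or 2.

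The responses to WT UTX differed between the 2 THP-1 sets in many genes. Over 13175 genes tested in both, the fold changes had a Spearman correlation of 0.0704 across genes, which are not independent replicates. Both sets raised 979 genes (809.2 if independent) and lowered 698 (562.1), and 1409 went opposite ways (1381.5). A direct test of the difference, with both sets in 1 fit, called 6376 genes, 48.4% of those tested, 2039 of them by at least 2-fold. The 3092 genes raised and 3210 lowered in batch2 were then tested as sets in the 9 comparisons of the first set, and 11 of 18 pairs passed 0.05. In WT against Vector neither set passed (medians 0.03 and 0.01, adjusted p = 0.306 and 0.394). In del-cIDR against Vector the raised set was higher and the lowered set lower (medians 0.04 and -0.05, adjusted p = 0.000386 each), and both passed in eIFIDR against Vector as well (0.10 and -0.09, adjusted p = 0.000453 and 0.000558). FUSIDR (adjusted p = 0.000386 and 0.0103, the latter adjusted p = 0.0592 with an estimated correlation) and del-TPR (adjusted p = 0.000446 and 0.000386) followed. In WT against eIFIDR the raised set was lower and the lowered set higher (adjusted p = 0.0236 and 0.0196, the latter adjusted p = 0.0678 with an estimated correlation).

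In mouse embryoid bodies, UTX-KO against WT asks what differentiating cells need UTX for. Blood genes were nearly lost: Hba-a1 (-9.56 ± 1.43), Hba-x (-9.52 ± 0.306), Hbb-bh1 (-8.44 ± 0.158), Hbb-b1 (-6.75 ± 0.827) and Hbb-y (-6.60 ± 0.64) encode embryonic and adult globins. Kel, Hemgn, Rhag, Cldn13 and Csf2rb2, of red cell membranes and blood progenitors, were at least 34.2-fold, 19.6-fold, 19.1-fold, 11.3-fold and 10.5-fold lower, with 0 counts in UTX-KO; Csf2rb2 has a close paralog and is uncertain. Genes of the developing nervous system rose: the patterning factors Msx3 (6.08 ± 1.54), Nr2f1 (5.28 ± 0.437), Tfap2b (4.21 ± 0.582) and Zic1 (4.03 ± 0.585), the neural Pou3f2 (4.57 ± 0.538), the signal Wnt1 (4.37 ± 0.357), the neural catenin Ctnna2 (4.05 ± 0.546) and A830082K12Rik (5.45 ± 1.54). Pax5, a regulator of B cells and midbrain, was at least 24.3-fold higher. Of 13799 genes tested 3425 rose and 3560 fell, 640 and 976 by at least 2-fold. DESeq2 called 4388.

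In the blood and endothelium list 1 of 19 measured genes rose and 18 fell, 19 adjusted over the list alone, with a median of -1.84 (adjusted p = 7.22e-12). The erythroid regulator Gata1 (-5.98 ± 0.542) was lower. In the mesoderm and cardiac list 3 of 26 measured genes rose and 19 fell, 22 adjusted over the list alone, with a median of -1.14 (adjusted p = 9.69e-07). The limb and heart regulators Tbx4 (-3.65 ± 0.146), Tbx5 (-3.48 ± 1.11) and Tbx20 (-2.56 ± 0.11) were lower. Hox genes fell with Hoxc6 (-3.42 ± 1.11), Hoxb5 (-3.19 ± 0.375) and Hoxc10 (-3.02 ± 0.447) (2 up and 19 down of 24, 21 adjusted over the list alone, median -1.62, adjusted p = 3.24e-06). Fibroblast genes fell with the collagen Col3a1 (-3.79 ± 0.0922) and the matrix protein Postn (-3.12 ± 0.075) (0 up and 12 down of 14, 12 adjusted over the list alone, median -2.13, adjusted p = 1.06e-09), and trophoblast genes with Hand1 (-2.04 ± 0.0358) and Plac1 (-1.73 ± 0.168) (1 up and 7 down of 10, 8 adjusted over the list alone, median -1.08, adjusted p = 0.000252). Neuroectoderm genes rose with Pax3 (3.26 ± 0.25) (17 up and 2 down of 19, 19 adjusted over the list alone, median 1.36, adjusted p = 5.48e-06), and naive pluripotency genes with Nr0b1 (1.86 ± 0.188), Esrrb (1.48 ± 0.0564) and Prdm14 (1.44 ± 0.161) (17 up and 2 down of 20, 19 adjusted over the list alone, median 0.81, adjusted p = 9.69e-07). Cell cycle genes rose slightly, for example Rrm2 (0.45 ± 0.0345) (18 up and 1 down of 24, 21 adjusted over the list alone, median 0.20, adjusted p = 8.04e-05). Germ line genes, with Nanos3 (1.35 ± 0.448) up, gave 5 up and 1 down of 9, 7 adjusted over the list alone, median 0.47, adjusted p = 0.0192, or adjusted p = 0.0841 with an estimated correlation, and COMPASS and Polycomb genes, with the Y-linked paralog Uty (-1.85 ± 0.181) down and Cbx7 (1.08 ± 0.0767) up, gave 10 up and 2 down of 23, 12 adjusted over the list alone, median 0.14, adjusted p = 0.0201, or adjusted p = 0.0839 with an estimated correlation. Endoderm genes went both ways, with Cubn (2.14 ± 0.0642) and Foxa2 (1.89 ± 0.142) up and Afp (-1.79 ± 0.0741) down (11 up and 7 down of 23, 18 adjusted over the list alone, median 0.40, adjusted p = 0.11). The list of primitive streak and mesendoderm genes, with Wnt3a (3.42 ± 0.597) up, gave 3 up and 8 down of 14, 11 adjusted over the list alone, median -0.55, adjusted p = 0.16. Formative and primed genes, with Fgf5 (-1.79 ± 0.158) down, gave 4 up and 5 down of 12, 9 adjusted over the list alone, median -0.07, adjusted p = 0.642, and hypoxia and glycolysis genes, with Ndrg1 (-0.83 ± 0.0752) down, gave 10 up and 5 down of 17, 15 adjusted over the list alone, median 0.11, adjusted p = 0.12.

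**Figure D3:**
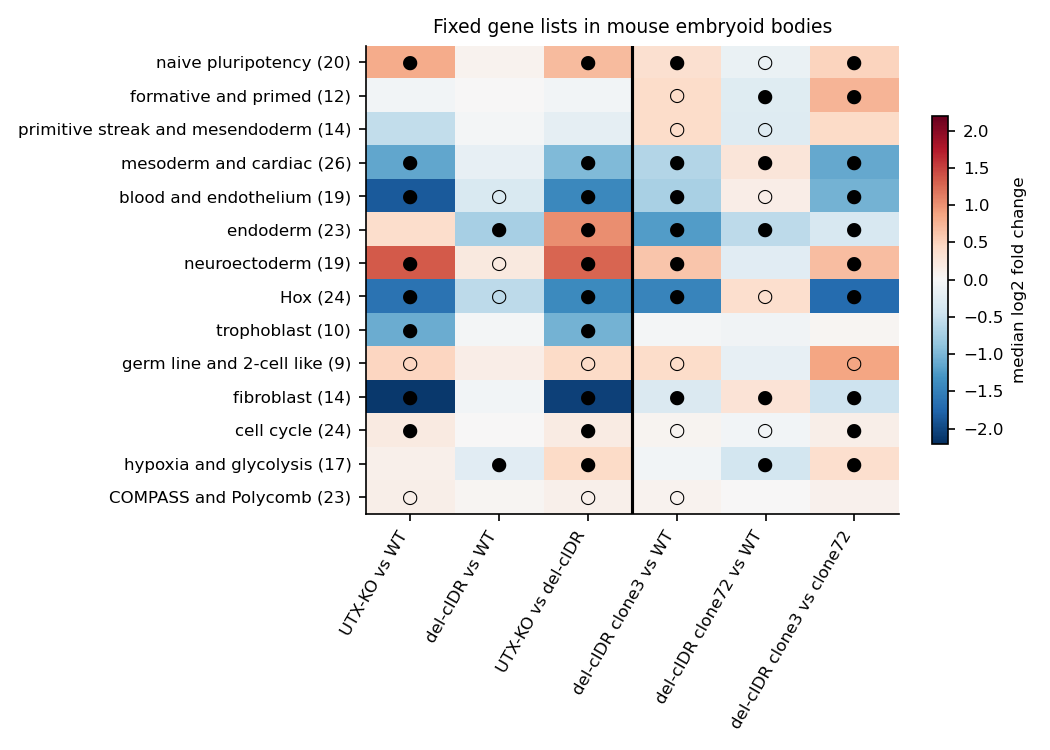
Median log2 fold change of each fixed mouse gene list (vertical) in each comparison of embryoid bodies (horizontal), with dots as in the plot of THP-1 lists. Blood and endothelium, mesoderm and Hox lists are low in UTX-KO and in clone3, while in clone72 their medians are above 0.

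The mean of both del-cIDR clones was set against WT, though clone72 also lacked transcripts of Y-linked genes. Visceral endoderm genes fell: the lipoprotein Apoa2 (-3.57 ± 0.842), the plasma protein Spp2 (-3.31 ± 0.672) and alpha-fetoprotein Afp (-2.53 ± 0.073). So did the imprinted growth genes Igf2 (-3.11 ± 0.0199) and Igf2r (-2.64 ± 0.0438) and the imprinted Klf14 (0.2398 CPM against 3.33 in WT, with 0 counts in 1 clone) and Zim1 (-2.70 ± 0.351), next to Lgals2 (-2.51 ± 0.405); Igf2os (-2.89 ± 0.126) and Gm44504 (-3.73 ± 0.385) overlap other genes and are uncertain. Pax5 was at least 3.01-fold higher, and Arg1 (1.73 ± 0.683), which breaks down arginine, the laminin Lama2 (1.65 ± 0.555), the meiotic Stra8 (1.43 ± 0.406), Zfp600 (1.36 ± 0.467), Smpdl3a (1.33 ± 0.466), Lrrc4 (1.31 ± 0.445), 4930429B21Rik (1.26 ± 0.419), the mesenchymal regulator Foxc2 (1.26 ± 0.23) and the activin subunit Inhba (1.20 ± 0.205) rose. In the endoderm list 1 of 23 measured genes rose and 17 fell, 20 adjusted over the list alone, with a median of -0.73 (adjusted p = 1.55e-14). Apoa1 (-1.79 ± 0.121) and Ttr (-1.69 ± 0.122) also fell. In the hypoxia and glycolysis list 0 of 17 measured genes rose and 16 fell, 16 adjusted over the list alone, with a median of -0.25 (adjusted p = 7.04e-12). The fall was mostly in clone72 (0 up and 17 down of 17, 17 adjusted over the list alone, median -0.41, adjusted p = 1.72e-17), and clone3 did not pass (3 up and 7 down of 17, 10 adjusted over the list alone, median -0.06, adjusted p = 0.107). Blood and endothelium genes, with Hbb-y (1.07 ± 0.0756) up and the endothelial Cdh5 (-0.67 ± 0.0448) down, gave 3 up and 11 down of 19, 17 adjusted over the list alone, median -0.34, adjusted p = 0.000249, or adjusted p = 0.055 with an estimated correlation. Hox genes, with Hoxb5 (-1.65 ± 0.233) down, gave 1 up and 9 down of 24, 11 adjusted over the list alone, median -0.58, adjusted p = 0.000377, or adjusted p = 0.0948 with an estimated correlation, and neuroectoderm genes, with Pax6 (1.00 ± 0.37) up, gave 3 up and 0 down of 19, 3 adjusted over the list alone, median 0.21, adjusted p = 0.00322, or adjusted p = 0.0948 with an estimated correlation. In all 1122 genes rose and 1304 fell, 30 and 90 by at least 2-fold. DESeq2 called 842. All tests here leave out the spread between clones. Kdm6a did not pass (0.11, adjusted p = 0.139).

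The 2 clones differed from each other in 5071 genes, 2511 higher and 2560 lower in clone3, against 4047 between clone3 and WT and 2464 between clone72 and WT. In clone3 the Hox list gave 0 up and 13 down of 24, 15 adjusted over the list alone, median -1.45, adjusted p = 2.25e-09 against WT, and in clone72 6 up and 1 down of 24, 7 adjusted over the list alone, median 0.37, adjusted p = 0.000374, or adjusted p = 0.0611 with an estimated correlation. The difference between clones was tested directly: Hox genes, with Hoxb2 (-2.46 ± 0.251) and Hoxd4 (-2.31 ± 0.529) lower in clone3, gave 0 up and 21 down of 24, 22 adjusted over the list alone, median -1.70, adjusted p = 1.99e-11. Mesoderm and cardiac genes, with Tbx5 (-3.20 ± 0.897) lower in clone3, gave 3 up and 19 down of 26, 22 adjusted over the list alone, median -1.13, adjusted p = 1.99e-08, and blood and endothelium genes, with Cdh5 (-1.52 ± 0.0653) lower, gave 1 up and 17 down of 19, 18 adjusted over the list alone, median -1.04, adjusted p = 6.19e-10. Naive pluripotency genes, with Lefty1 (1.25 ± 0.0871) higher, gave 15 up and 1 down of 20, 18 adjusted over the list alone, median 0.49, adjusted p = 1.30e-06, and hypoxia genes, with Ndrg1 (1.18 ± 0.0814) higher, gave 15 up and 0 down of 17, 15 adjusted over the list alone, median 0.36, adjusted p = 9.68e-08. Endoderm genes were lower than WT in both clones (2 up and 19 down of 23, 21 adjusted over the list alone, median -1.23, adjusted p = 2.13e-11 in clone3, 2 up and 12 down of 23, 15 adjusted over the list alone, median -0.57, adjusted p = 2.35e-06 in clone72). Both clones raised 332 genes and lowered 272 (185.2 and 175.4 if independent, simulated 0 and 0 with shared WT libraries, covariance difference 0.00544), and 604 went opposite ways. By at least 2-fold both clones raised 7 genes and lowered 35, the latter holding Afp, Apob, Amn, Trf, Fga and Igf2, named after their values were seen. UTX-KO shared 1123 rises and 1472 falls with clone3 (486.5 and 538.4; simulated 0 and 0; covariance difference 0.145), with 404 opposite, and 262 and 369 with clone72 (323.7 and 299.3; simulated 0 and 0; -0.0122), with 1056 opposite. Uty, the Y-linked paralog of Kdm6a, stood at 149% of its WT CPM in clone3, 26.5% in UTX-KO and 0.266% in clone72, and the Y-linked Ddx3y at 157%, 38% and 0.416%. Eif2s3y and Kdm5d, also on the Y, were at 27.4% and 11.8% in UTX-KO, so all 4 measured Y genes were lower there. In ES cells, with 1 library each, Ddx3y was at 138%, 17% and 0.182%.

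UTX-KO against the mean of the del-cIDR clones also gave lower globins, with Hba-x (-9.65 ± 0.306), Hba-a1 (-9.51 ± 1.43) and Hbb-bh1 (-8.45 ± 0.158), and Kel and Hemgn at least 30.5-fold and 28.2-fold lower. Msx3 (5.49 ± 0.952), Klf14 (3.335 against 0.2398 CPM), Pou3f2 (4.96 ± 0.479) and Nr2f1 (4.51 ± 0.26) were higher in UTX-KO. In the endoderm list 16 of 23 measured genes rose and 3 fell, 20 adjusted over the list alone, with a median of 1.03 (adjusted p = 2.17e-06). Its members Apoa2 (4.02 ± 0.831), Cubn (3.65 ± 0.0784) and Apob (3.21 ± 0.0579) were higher in UTX-KO. In the blood and endothelium list 1 of 19 measured genes rose and 17 fell, 18 adjusted over the list alone, with a median of -1.41 (adjusted p = 3.44e-10). In all 3585 genes were higher and 3594 lower, 600 and 876 by at least 2-fold, and DESeq2 called 4683. These p-values also leave out the spread between clones.

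ES cells had 1 library per genotype, so the values have no test. In UTX-KO 162 of 11560 genes were at least 2-fold higher and 533 lower than in WT. Trophoblast genes had a median log2 ratio of -2.67 there and fibroblast genes -1.65, both below all of 10000 random lists of like expression, and germ line genes had -1.10. In both clones 8 genes were 2-fold higher and 3 lower. Endoderm genes had a mean ratio over clones of median -0.21, above 0.93% of random lists, and neuroectoderm genes 0.24, above 100% of them.

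UTX ChIP-seq peaks were 648 in Vector, 15548 in WT and 11129 in del-cIDR on the autosomes and X of GRCh38. The file labels name the Vector library as the control of the WT and del-cIDR lists, so these lists hold little of the Vector list by construction (0.521% of WT peaks). Of WT peaks 18.0% overlapped a del-cIDR peak, against 0.373% after moving the peaks by 1 Mb, and 25.2% of del-cIDR peaks overlapped a WT peak. Peaks lay within 2.5 kb of a gene end in 11.5% of WT and 15.2% of del-cIDR peaks (7.51% and 7.93% after moving). The WT peak with the lowest q lay at BAP1, a tumour suppressor deubiquitinase (chr3:52403037-52403896, 8.09-fold over control). Of the 10 with the lowest q 6 crowd on chromosome 1, among them 1 near RIMS3 (chr1:40618584-40618960, 4.06-fold), as do 4 of 10 in del-cIDR. Of WT UTX peaks 17.6% overlapped an H3K4me1 peak of WT (3.97% after moving), 17.8% an H3K27ac peak (3.80%) and 8.31% an H3K4me3 peak (2.12%). H3K4me2 peaks held 2.82%, below the moved share of 3.83%. The Polycomb mark H3K27me3, the substrate of UTX, held 5.5% in Vector and 2.93% in WT (0.881% and 0.508% after moving). MLL4, the H3K4 methyltransferase that works with UTX, held 10.5% in Vector, 2.53% in WT and 5.11% in del-cIDR, from lists of 50813, 5229 and 16975 peaks. Peaks of both constructs lay on WT H3K27ac in 21.1%, peaks of WT alone in 17.1% and peaks of del-cIDR alone in 11%. Each ChIP list is from 1 library, and list sizes follow depth as well as signal.

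**Figure D4:**
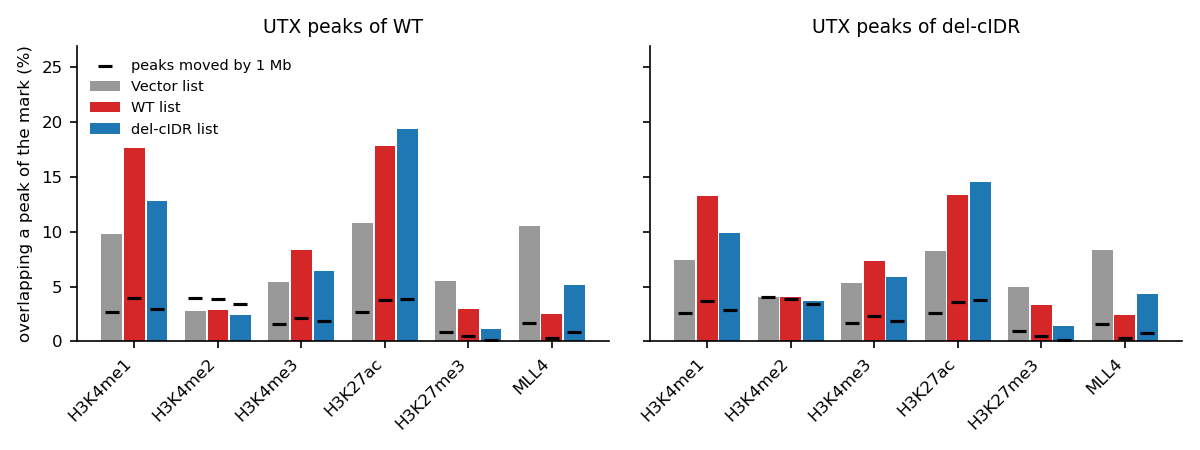
Share of UTX peaks (percent, vertical) of WT (left) and del-cIDR (right) that overlap a peak of each mark or of MLL4 (horizontal), with bars for the lists of Vector, WT and del-cIDR and black dashes for the same UTX peaks moved by 1 Mb. WT UTX peaks reach 17.6% on H3K4me1 and 17.8% on H3K27ac of WT, and on the H3K4me2 lists they stay below the dashes.

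H3K27me3 lists held 27230 peaks in Vector, 12389 in WT, 2342 in del-cIDR and 9473 in MT2, and H3K27ac lists 71028, 114327, 117746 and 85121. H3K4me1 lists held 72312, 110694, 83914 and 129508 peaks in the same order. Across KDM6A (chrX:44873188-45112779) PRO-seq had 0 peaks in both Vector, 21 in each WT and 15 and 19 in del-cIDR lists. H3K27me3 had 15, 3 and 9 in that order. Transgenes may add reads there. PRO-seq lists held 64814 and 37698 peaks in Vector, 57674 and 51625 in WT and 33802 and 43122 in del-cIDR. Within 1 group 39.6% to 79.2% of peaks recurred in the other list. Of 12722 expressed genes 81.2% and 77.7% had a peak at a gene end in Vector, 81.9% and 81.6% in WT and 72.1% and 79.6% in del-cIDR, against 12.3% to 19.6% after moving. The WT and Vector shares differed by less than the spread of Vector, and 2 lists per group cannot reach p below 0.05 in an exact test.

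HiChIP asks which promoter and enhancer contacts follow each construct. Loop lists held 31933 to 40778 loops in the first H3K4me3 batch, 57626 in Vector, 67741 in WT, 88981 in del-cIDR, 95676 in eIFIDR and 90554 in del-TPR in the second, and 20912 to 37811 at H3K27ac. Of WT loops 66.3% were also listed in Vector in the first batch, 60.8% in the second and 51.0% at H3K27ac. At equal length, replicate lists of the first batch shared 76.7% to 79.4% of loops and lists of different constructs 65.3% to 67.5%. Over loops with at least 100 counts in a pair of lists the variance ratio to counting error was 0.375 to 0.458 for replicates, which were counted as 1, and 1.13 to 1.35 for different constructs. In all 3 sets 92 loops were listed in WT and not in Vector, and 16 the reverse. For del-cIDR these numbers were 160 and 7 and for eIFIDR 122 and 12, but the lists differ in length, and the first batch alone, with lists of like length, gave 5101 and 5107 for WT. The loops in WT and not in Vector included loops at KMT2C, an H3K4 methyltransferase (chr7:152435001-152465000), between SLC25A38 and RPSA, and at MEF2D, a myeloid leukaemia regulator, named after their values were seen. Loops in WT and not in del-cIDR numbered 31, with anchors at GFI1 and between ASXL1 and PLAGL2 among them, and 110 were in del-cIDR and not in WT. WT UTX peaks lay at an anchor of 8.65% to 9.48% of loops in the first H3K4me3 batch (7.67% to 7.92% after moving) and 8.4% to 9.23% in the second (7.08% to 7.44%). At H3K27ac the shares, 6.38% to 7.64%, were below those after moving in each of the 5 lists (7.19% to 7.83%). In each set the share was highest in Vector. Over 5106 loops listed throughout, the deviations of a construct correlated between sets at 0.195, 0.146 and 0.199 on average, in a comparison chosen after seeing the data. The right matching of the 4 constructs gave the highest mean of 24 matchings each time (exact one-sided p = 0.0417, the smallest possible), and loops are not independent replicates.

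Of genes lower in first-set WT than Vector, 62.9% had a WT UTX peak within 50 kb (51.2% after moving), against 58.0% of others. The odds ratio was 1.23 (Fisher's two-sided adjusted p = 0.000838 over 64 tests, none matched for gene length). Genes higher in WT had one in 58.8% (48.3%), as did others. Within 2.5 kb the shares were 7.44% against 8.44% for genes higher in WT (adjusted p = 0.212) and 8.91% against 8.05% for genes lower (adjusted p = 0.389). Peaks of del-cIDR gave 51.0% against 46.6% within 50 kb of genes lower in WT (adjusted p = 0.00181). Loop numbers at changed genes, WT minus Vector, passed 0.05 in 0 of 48 permutation tests after adjustment, with a lowest adjusted p of 0.433 and 5 tests below 0.05 unadjusted. Of 30 named genes IDO1, MGAT3 and, perhaps by transgene reads, KDM6A had a WT UTX peak within 2.5 kb.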

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

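In this part the tests of KDM6A dilution, of Y chromosome loss and of a slower exit from pluripotency were chosen only after the result was seen.

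WT against Vector differed between the first THP-1 set and batch2 in 6376 genes by a test of the difference itself. A transcript length bias of batch2 Vector is argued against as the whole cause, since batch2 fold changes correlated with length at 0.0612. Those of the first set did at -0.187 and of MT2 against WT at -0.153, but after centring on length the responses of both sets still correlated at only 0.0898. Without RNR1, RNR2 and TALAM1, whose share is high in batch2 Vector, the correlation of the fold changes was 0.0731. That decides nothing, although a value below 0.2 was set beforehand as evidence against this cause, since under the scaling used it left 99.1% of calls in place. Dilution of the response by KDM6A transcript in batch2 Vector, expressed there or carried over between libraries, stays open too. Genes changed by at least 2-fold were 2031 in batch2 against 377, but that count holds whatever else sets these Vector libraries apart, and the interferon median was lower in batch2 and the monocyte-macrophage median higher. The batch cannot be told apart from any difference between the cultures, since each set is 1 batch with its own Vector libraries. No biological explanation was tested, as the labels name none.

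Embryoid bodies of the 2 del-cIDR clones differed from each other in 5071 genes, though both carry the same deletion. A difference already present in ES cells stays open. The clone differences of both stages correlated at 0.0331, or 0.0737 over the 4253 genes called between clones, below the 0.1 set beforehand as evidence against it, but 1 ES library per clone cannot decide, and clone72 already lacked the Y-linked transcripts in ES cells. A slower exit of clone3 from pluripotency stays open. Against clone72 naive genes (median 0.49) and neuroectoderm (0.69) rose and 3 of 5 germ layer lists fell, all past the set test. Loss of the Y chromosome with Uty in clone72 was compared with UTX-KO, and the correlation was -0.436, but UTX-KO also had fewer Y-linked transcripts and is no clean reference. Only 1 clone lacks the Y genes, so their loss cannot be told apart from other differences between the clones, and a different course of differentiation may also play a part.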

How the results depend on the processing

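The setting without RNR1, RNR2 and TALAM1, with libraries thinned to 1 total or not, was chosen only after the data were seen. Counts of called genes under DESeq2 size factors, without the expression filter, with only the libraries compared, and with the replicate number as a block stayed within 1.5 times of those reported in all 15 comparisons. The excess of rises in WT, 59.8% of calls against Vector and 60.3% against del-cIDR, was 52.4% and 52.1% with only the libraries compared. The replicate numbers pair no libraries, since residuals of equal numbers correlated at most at 0.086 over 24 pairs of groups, and the replicate block gave 5918 genes for WT against Vector, 6378 in batch2 and 6930 for UTX-KO. The DESeq2 test called fewer genes everywhere: 3343 for WT, 2001 for del-cIDR, 2623 for FUSIDR and 1322 for del-TPR against Vector, and 3687 for WT, 4747 for eIFIDR and 2068 for FUSIDR against del-cIDR. It called 1739 for MT2 against WT, 4388 for UTX-KO and 842 for del-cIDR against WT embryoid bodies, and 4683 for UTX-KO against del-cIDR. By at least 2-fold it called 240 for WT (377 reported), 152 for FUSIDR (300) and 2 for del-TPR (64) against Vector. Against del-cIDR it called 175 for WT (321), 191 for eIFIDR (404) and 97 for FUSIDR (245), and 62 for MT2 against WT (186) and 58 for del-cIDR embryoid bodies (120), and the rest stayed within 1.5 times. The cause was not tested.

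Leaving out 1 library, with the lone sample assumed to vary like the other groups, moved 3 counts by over 1.5 times, and fewer samples are then in the fit. For del-TPR against Vector the range was 1771 (without Vector replicate 1) to 2444, with 1983 without del-TPR replicate 2. For MT2 against WT it was 2349 (without WT replicate 1) to 3052, with 2373 without WT replicate 2. For del-cIDR against WT embryoid bodies it was 1481 (without WT replicate 1) to 2182, with 1497 without WT replicate 2. Clone3 alone gave 4047 there. MT2 against WT fell to 1502 calls without the 3 genes in thinned libraries, where fewer counts remain. Of 1954 values of named genes under these settings 1860 stayed past the threshold, 94 no longer passed and 0 reversed.

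Of the list tests in THP-1 cells 78 passed, against 38 with an estimated correlation and 134 with fry, which does not compare a list with other genes. Only peaks with a negative log10 q of at least 5 left 7665 WT UTX peaks, of which 15.9% overlapped del-cIDR peaks, with 3.31% on H3K27me3 and 3.04% on MLL4 of WT, and 76.3% and 79.1% of genes with a PRO-seq peak in Vector and WT. An overlap of at least 50% of the shorter peak gave 16.9% for del-cIDR, 16.7% for H3K4me1, 2.34% for H3K4me2, 7.53% for H3K4me3, 16.6% for H3K27ac and 2.65% for H3K27me3, as a stricter overlap must be lower. HiChIP loops of WT listed in Vector rose to 83.8%, 81.0% and 72.8% with anchors within 10 kb. A 10-fold stricter rate gave 60.2% in the second H3K4me3 batch, and lists of equal size gave 65.8% there and 59.3% at H3K27ac. The odds ratio of a UTX peak within 2.5 kb of genes up in WT was 1.08 with batch2 calls, against 0.873 (neither past 0.05). Within 1 kb of genes down in first-set WT it was 1.36, past 0.05. With a prior count of 0.5, 5 genes were 2-fold lower in both ES clones. The cause of these moves was not tested further. In batch2 37.3% of log2 changes of 0.5 were recovered, against 68.7% in embryoid bodies, deeper than batch2 Vector. Batch2 also had a higher common BCV (0.0283 against 0.0119) and 3 residual degrees of freedom, so a limit by depth was not separated from these.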

Other observations

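Lists and tests here, bar interferon medians, were chosen only after the result was seen.

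Targets of ATF4, the regulator of the amino acid response, rose together in the chimeras. Outside the genes named for eIFIDR, 23 of 23 measured targets were higher in eIFIDR than in Vector, with a median of 1.474 (adjusted p = 4.88e-18). In FUSIDR 21 of 23 rose, with a median of 0.6 (adjusted p = 4.41e-16), while in WT 7 rose and 8 fell (median -0.04, adjusted p = 0.502). Against del-cIDR the eIFIDR median was 1.23 with 23 higher. Some targets, such as TRIB3 and ATF3, are also in the fixed lists. Examples are the glycine transporter SLC6A9 (5.57 ± 1.02), the serine synthesis enzymes PSAT1 (2.65 ± 0.0285) and PHGDH (2.24 ± 0.0272), and NUPR1 (2.61 ± 0.123).

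Genes of glycolysis and the oxygen response, the human counterparts of the mouse hypoxia list, were lower in WT than in Vector, where 15 of 17 fell with a median of -0.44 (adjusted p = 2.02e-11). Against del-cIDR 17 of 17 were lower in WT (median -0.87, adjusted p = 3.32e-16), while del-cIDR was above Vector with 13 of 17 higher (median 0.19, adjusted p = 9.10e-08). Examples in WT against del-cIDR are BNIP3 (-1.62 ± 0.036), the glucose transporter SLC2A3 (-1.59 ± 0.0969) and PDK1 (-1.33 ± 0.0683); ADM and EGLN3, also members, were among the named genes. In batch2 WT against Vector 7 rose and 7 fell (median -0.01, adjusted p = 0.918), and 15 of 17 were lower in MT2 than in WT (median -0.78, adjusted p = 2.36e-12). Cholesterol synthesis genes fell in WT against Vector, 14 of 20 including DHCR7 (-0.57 ± 0.0688), with a median of -0.18 (adjusted p = 1.59e-05). Each of these calls in WT, del-cIDR and MT2 held with an estimated correlation.

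Imprinted genes differed between the mouse lines more often than other genes. Between the clones 9 of 48 differed by at least 2-fold, against a mean of 2.07 in 10000 random lists of like expression, of which 99.97% gave fewer. In clone3 Dlk1 (-4.30 ± 0.176), Cdkn1c (-2.06 ± 0.109) and Peg13 (-3.68 ± 0.343) were lower than in WT, while Igf2 and Igf2r were lower in both clones and in UTX-KO (-1.28 and -1.2), and in UTX-KO Meg3 (-3.95 ± 0.0842), Rian (-3.42 ± 0.0723) and Mest (-3.05 ± 0.0284) were lower and Grb10 (2.59 ± 0.0738) higher. Imprints can differ between ES cell lines by culture history as well as by genotype, so a drift of single lines is a candidate explanation for what differs between the clones. Igf2 and Igf2r fell alike in both and also in UTX-KO, so the WT line, of which there is 1, may be the odd one.

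Interferon response genes were higher than Vector in each of the 5 constructs of the first set. Vector libraries that are low by accident would raise all 5 medians alike and stay open: in batch2, with other Vector libraries, the list median of WT was 0.311 without passing an estimated correlation. They do not account for differences between constructs, such as a median of 0.983 for eIFIDR against del-cIDR. The amount of transcript is argued against as the whole cause, since del-TPR, with the highest KDM6A level, had the lowest median, 0.476. That any added disordered region raises these genes is argued against by FUSIDR against del-cIDR, at -0.255. A part of the rise that all constructs share, such as transduction or transgene expression, may remain, and no group expresses an unrelated transgene.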
